A study of Mus musculus with 4 samples.

How the data were processed

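Total RNA from naive and memory CD8 T cells was isolated with Trizol and made into cRNA for hybridisation by the manufacturer's protocol, per the labels. Each population was read on the A and the B chip of a 2-chip Affymetrix mouse set, which gave 4 arrays. Whether the arrays of a population share an RNA extract is not given in the sources used here. The deposited values are array intensity values, 1 whole number per probe set, and they include negative numbers. The software that made them, its settings and any genome build are not given in the sources used here. The deposited intensity values had a 2% trimmed mean close to 150 on every array (150.2, 150.2, 150.3 and 150.4), so they appeared to be scaled already. No detection call was used here. No scanner images or probe-level signals were used here, so background subtraction and summarisation of probes could not be varied.

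Samples were grouped by their titles, and the chip of each column was taken from the table that holds it. Every column was matched to a sample. There were 6584 probe sets on the A chip and 6595 on the B chip, 55 of them controls on each. Gene symbols came from the array platform annotation, checked by Entrez gene number against a RefSeq gene table of assembly GRCm38.p6, which used 5551 and 1993 numbers and changed 0 symbols. On the A chip 5560 probe sets had 1 symbol, 197 several and 827 none listed. On the B chip 2001 had 1 symbol, 27 several and 4567 none listed. Probe sets with several symbols or none were counted but never named, and no coordinates are given because the sources name no genome build for the arrays.

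Control probe sets were left out, and both arrays of a chip were scaled to the same 2% trimmed mean (factors from 0.993 to 1.01). The floor of a chip was the 95th percentile of the sizes of the negative values, taken from the noisier array (296 on A, 423 on B). Values under the floor were set to it before the log2 ratio of memory to naive was taken, and a fold against the floor is given as at least that size. A probe set was called higher or lower when its brighter array was at least 2 times the floor and the ratio was at least 2-fold. A gene was represented by its brightest probe set and counted as measured when 1 array or both lay above the floor. On the B chip 462 of 1760 genes were measured, of which 41 were higher, 40 lower and 381 neither. Genes described as neither or within 2-fold include some with an array under the floor, whose ratio is only a bound. For each of 28 gene lists, the median over measured members was placed among 10000 random lists of the same size, matched in 10 bins of mean intensity, and at least 3 measured members were required. The gene lists, thresholds and comparisons and most alternative settings were fixed before the data were examined, as were 4 of the 8 tests of explanations in the closing section.

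The rule for named genes took the 12 largest and 12 smallest ratios among genes with 1 symbol and a brighter array at least 4 times the floor (120 genes on B). To these it added up to 4 members of each list that passed 2-fold, and 14 T cell genes to be given in any case, 1 of which is not reported here. Other list members are named with their values only as examples, and these were chosen after their values were seen.

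The plan pooled both chips for gene lists and named genes. Because the naive A values hardly followed their gene names, the B chip alone, which had been set beforehand as an alternative for the lists, was used in place of the pool, and the same was done for named genes. This decision was made after the data were seen. Pooled or A-chip medians are given with the alternatives for some of the lists they moved or turned, not for every such list. Ratios were never formed between chips.

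With 1 array per group and chip there is no estimate of error, and the number of arrays limits the precision. The alternative settings fixed beforehand were no scaling, scaling by the median ratio, quantile normalization, the floor halved and doubled, only probe sets without a class letter in their name, size thresholds of 1.5-fold and 3-fold, other limits on dim probe sets, the mean of all probe sets of a gene, other sets of chips, and only genes above the floor on both arrays. Intensity-dependent (lowess) normalization with a span of 0.4 and the removal of sequence-family probe sets, whose probes match several related genes, were added after the data were seen. No array could be left out in turn. The procedure was tested on simulated data made from the B-chip values of 6540 probe sets. It recovered 200 of 200 simulated 4-fold changes, called 0 in the wrong direction, and called 41 unchanged probe sets (0.647%). That share is of all unchanged probe sets, whereas in the real data 522 were bright enough to be called and 180 were called. Changes were planted only in bright probe sets, and no bend at the bright end was simulated. The test therefore does not show how well 2-fold differences or the brightest probe sets are called. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.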

Results

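The series measured gene expression in naive and memory CD8 T cells of B6.2.16 mice, whose T cells carry a transgenic receptor for the male HY antigen. All donor and host animals were female and lacked RAG1, a recombinase without which no other T or B cells form. Naive cells came from lymph nodes at a stated purity above 85%. For memory cells, splenocytes were cultured with HY peptide for 4 days, transferred into hosts, and recovered after 200 days from spleens and lymph nodes by magnetic bead sorting at a stated purity above 80%. RNA of each population was read on a set of 2 Affymetrix mouse chips, A and B, which gave 4 arrays, with 1 memory and 1 naive array per chip. No group had a replicate on a chip, so no spread between samples, no p-value and no standard error could be given. Differences are described by size, and each compares 1 pair of arrays, not the conditions at large. Tissue of origin, culture, transfer, age and sorting all changed together with the group.

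The values were intensities, of which 19.8% (memory) and 22.7% (naive) on the A chip and 34.0% and 35.6% on the B chip were below zero. After scaling, signals under 296 on the A chip and under 423 on the B chip were treated as noise. On the B chip the memory and naive arrays tracked each other, with a Spearman correlation of 0.85 across 6540 gene probe sets. On the A chip the correlation was 0.10 across 6529 probe sets. The 55 control probe sets printed on both chips separated the arrays in the same way. Their correlation between chips was 0.96 for the memory arrays and 0.21 for the naive arrays, and the memory A array correlated with the naive B array at 0.88. For 400 genes with probe sets on both chips, the naive A values correlated with the naive B values at 0.073, inside the range of -0.091 to 0.093 given by shuffled gene names, whereas the memory A values correlated with the naive B values at 0.42. The naive A values correlated with the memory A values of these genes at 0.18, above that range, which was made for the naive B values. The brightest value of a gene was taken per array, so genes with more probe sets can raise a correlation within a chip. These correlations are across genes or probe sets, which are not independent replicates. The naive A values therefore followed the genes they are listed for weakly at most, and no gene is compared between the groups on the A chip. The gene comparisons below are those of the B chip.

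**Figure D1:**
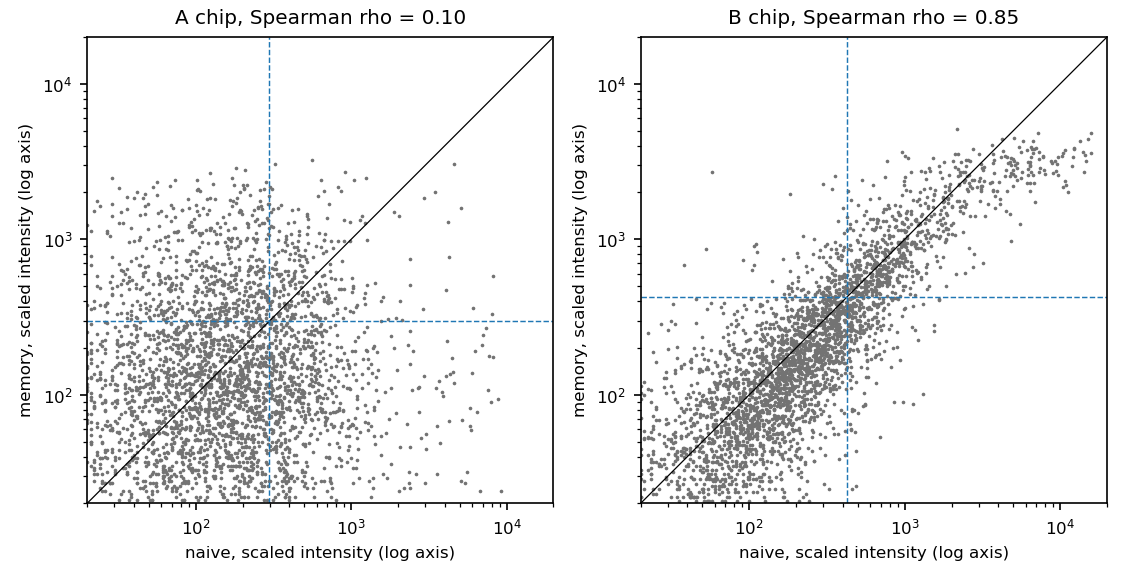
Scaled intensity of each gene probe set on the naive array (x axis, log scale) and the memory array (y axis, log scale) for the A chip (left) and the B chip (right), 1 array per group, with dashed lines at the noise floor, a solid line at equality, and values below the axis start left out. The B-chip points follow the line of equality and bend below it at the bright end, while the A-chip points form a cloud (Spearman correlations of 0.85 and 0.10).

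**Figure D2:**
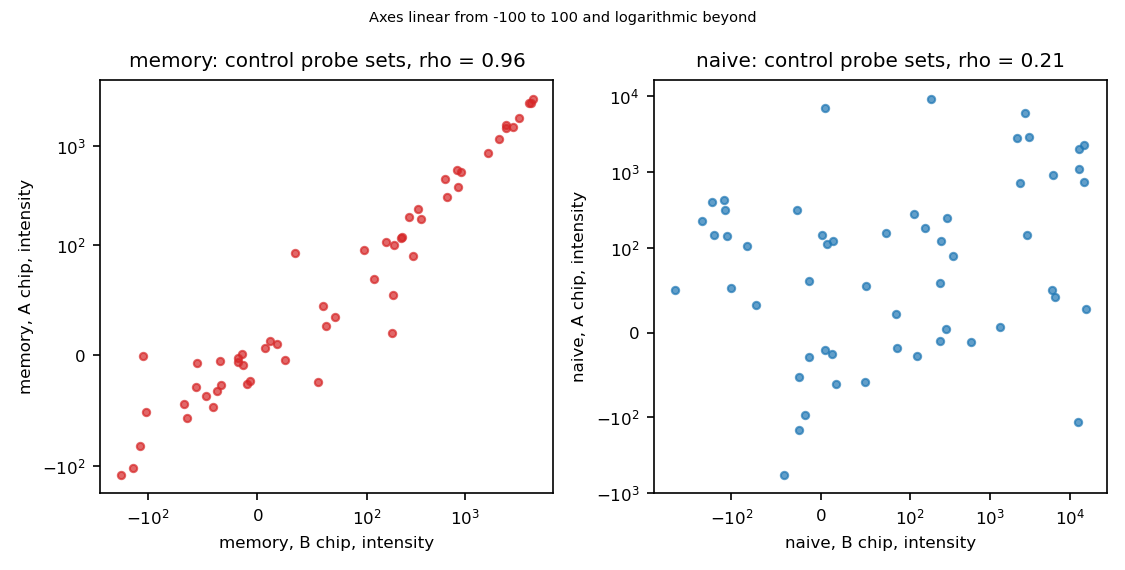
Intensity of the 55 control probe sets on the B chip (x axis) and the A chip (y axis) for the memory arrays (left) and the naive arrays (right), on axes that are linear near zero and logarithmic beyond. Control signals matched between the memory arrays (correlation 0.96) and hardly between the naive arrays (0.21).

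The first comparison asked which genes differ between memory and naive cells of 1 receptor specificity. On the B chip the named genes higher in the memory preparation included the interferon-induced Isg15 and several macrophage markers. Isg15, an interferon-induced ubiquitin-like protein, had the largest ratio, at least 6.06-fold (2560 against 355, the naive value under the floor). Mpeg1, a pore-forming protein of macrophages, was 3.84-fold higher (3665 against 954), and Ly6c2, a surface antigen carried by memory CD8 T cells and by monocytes, was 3.41-fold higher (3439 against 1009). The genes lower in memory included the transcription factors Lef1 and Ets1, the immediate early and stress genes Jund, Tnfaip3 and Ppp1r15a, and very bright transcripts of the translation machinery such as Eef1a1. In total 67 probe sets were at least 2-fold higher and 113 at least 2-fold lower in memory, among 1056 above the floor on at least 1 array. Of these, 42 and 45 had a single gene symbol, and 25 and 68 could not be named here. Of the named genes that differed, 13 of 17 higher and 11 of 23 lower ones were read by probe sets outside the sequence-family class, whose probes match several related genes, and Ly6c2 was not among these. The higher ones made up 37.2% of all that differed, and this share depended on the scaling: the split was 70 to 105 without scaling, and the share was 50.8% with scaling by the median ratio and 57.8% with quantile normalization. The corresponding A-chip counts were 444 higher and 418 lower among 2095, and they carry no gene-level meaning for the reason given above.

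Macrophage and monocyte markers had the highest percentile of the lists. Of 13 measured members, 6 were at least 2-fold higher, none was 2-fold lower and 7 lay within 2-fold. The median log2 ratio was 0.94, at percentile 100 of 10000 random lists matched on intensity, 95% of which lay between -0.49 and 0.37. Among the lists with a median, only this one, the naive transcription factors and the cell cycle genes lay outside the central 95% range of their random lists. The medians of the naive transcription factors and the cell cycle genes rest on memory values under the floor. Besides Mpeg1, the mannose receptor Mrc1 was 3.04-fold higher (1810 against 596), the macrophage colony-stimulating factor receptor Csf1r had a log2 ratio of 1.32 (2723 against 1090), and the lysosomal protease Lgmn was 2.48-fold higher (1148 against 463). The calls of Lgmn and Apoe were lost with the doubled floor, Mrc1 shrank to 1.10, and another Mpeg1 probe set, on the memory A array, read 96, under its noise limit of 184. The other members past 2-fold were Apoe, at least 2.37-fold higher (1002 against 260, under the floor), and the complement subunit C1qb, with a log2 ratio of 1.14. Many of these transcripts were also present in the naive preparation, and the adhesion molecule Vcam1 read 4443 against 4217. All 13 members had positive log2 ratios as reported and under the median-ratio, quantile and intensity-dependent scalings, and 7, 9 and 8 of them passed 2-fold. These scalings raise the ratios of most bright genes, so that outcome could hardly differ and adds no support. Without sequence-family probe sets 4 of 11 measured members passed 2-fold. With only genes above the floor on both arrays 5 of 12 did. The ratio of Vcam1, 0.08 as reported, became 1.44 with quantile and 1.10 with intensity-dependent normalization.

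Of 6 measured interferon response genes, 2 were at least 2-fold higher and 4 within 2-fold. The median of 0.75 lay at percentile 97.2, inside the 95% range of random lists from -0.40 to 0.77. Ifi204, an interferon-induced DNA sensor, was at least 2.22-fold higher (938 against 110). The immunoproteasome subunit Psmb9 had a log2 ratio of 0.94 (1.09 with median-ratio and 1.01 with intensity-dependent scaling) and the GTPase Ifi47 one of 0.55. Ifi204 no longer passed when the floor was doubled. Oas1g, counted within 2-fold, read 445 against 179, the naive value under the floor, so its 0.073 is only a lower bound. With the floor halved 3 of 7 measured interferon response genes were higher. With only genes above the floor on both arrays 0 of 3 were, because the naive values of Isg15 and Ifi204 lay under it. Without sequence-family probe sets, the class that reads Ifi204, 1 of 4 was higher. The interferon and macrophage lists share no member.

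Dendritic cell and MHC class II genes went both ways. Of 6 measured, 2 were higher, 1 lower and 3 within 2-fold, with a median of 0.22 at percentile 95.5. The class II chain H2-Ab1 was 2.48-fold higher (2500 against 1009) and the peptide-loading chain H2-DMb1 2.06-fold higher (1503 against 728). Cd74, the invariant chain that escorts class II molecules, was 3.10-fold lower (3068 against 9507), and the class II chains H2-Eb1 and H2-Aa had log2 ratios of -0.64 and 0.15. The call of H2-DMb1 was lost with the doubled floor, and that of Cd74 with quantile normalization (-0.69) and intensity-dependent normalization (-0.30). H2-DMa, counted within 2-fold, read 513 against -213, the naive value under the floor, so its 0.28 is only a lower bound. With the floor halved 3 of the 6 were higher.

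Other large differences towards memory were seen for genes outside these lists. The lipoprotein-associated phospholipase Pla2g7 was at least 4.99-fold higher (2111 against 340). The haemoglobin-binding plasma protein haptoglobin, Hp, was 4.71-fold higher (2032 against 431), and the actin-binding kinase substrate Marcks 3.96-fold (1784 against 450). The naive values of Hp and Marcks lay just above the floor, and their log2 ratios of 2.24 and 1.99 shrank to 1.26 and 1.08 when it was doubled, while the bounds of Isg15, Pla2g7 and Alas2 became 1.60, 1.32 and 1.20. The galactose-binding lectin Lgals3 was 2.38-fold higher (2366 against 995, with 61 and under the noise limit on the memory A array), and the cytochrome P450 gene Cyp2d10 2.26-fold (2242 against 990). Alas2, the first enzyme of haem synthesis in red cell precursors, was at least 4.60-fold higher (1944 against 183). The globin genes went the other way, with Hba-a1 5.63-fold lower (2007 against 11296) and Hbb-b2 2.67-fold lower (2290 against 6105). The ratio of Hba-a1 shrank to -1.34 with intensity-dependent normalization, and the call of Hbb-b2 was lost with quantile (-0.95) and intensity-dependent normalization (-0.60). The erythroid list thus held 1 higher, 2 lower and 1 member within 2-fold of 4 measured, with a median of -0.56 at percentile 33.0. With the floor doubled, or with only genes above the floor on both arrays, 3 members were left and the median was the ratio of Hbb-b2, -1.41.

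Memory and activation surface markers showed 2 of 7 measured members higher and 5 within 2-fold, with a median of 0.18 at percentile 76.2. The higher pair were Ly6c2 and Itgb1, the integrin beta-1 chain, which was 2.10-fold higher (1554 against 741) and was lost with the doubled floor. Cd44, a standard marker of antigen-experienced T cells, was not above the floor on either array (45.7 and 4.03). Cd8b1, Cd3e, Ccr7, Il7r, Il2rb, Ly6c1, Gzmb, Ifng and Bcl2 had no probe set with their symbol on the B chip and are not compared here.

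Of 6 measured genes of the T cell receptor complex, 5 lay within 2-fold with values under the floor set to it, with a median of -0.11 at percentile 68.0. The coreceptor chain Cd8a gave 498 in memory against 352 in naive, the latter under the floor, for a log2 ratio of at least 0.24. Cd3d, a chain of the signalling complex, had a ratio of -0.22. Its partner Cd3g read 254 in memory, under the floor, against 502, so its -0.25 is only a bound and a larger difference was not detectable. The exception was Thy1, a surface protein of all mouse T cells, which was 2.17-fold lower in memory (2848 against 6184). This call was lost with the median-ratio scaling, and the Thy1 ratio shrank to -0.34 with quantile normalization and -0.14 with intensity-dependent normalization.

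Of 3 measured naive and quiescence transcription factors, 2 were at least 2-fold lower, and the median of -1.40 lay at percentile 0.83, outside the random range of -1.04 to 1.01. Lef1, a partner of beta-catenin that is active in naive T cells, was at least 3.66-fold lower (256 against 1549). Ets1, a lymphoid transcription factor, was at least 2.64-fold lower (271 against 1114). The antiproliferative gene Btg1 had a log2 ratio of -0.44. Both memory values lay under the floor, and both calls were lost when the floor was doubled. On the memory A array another Ets1 probe set read 847, above that array's noise limit of 184. Of 3 measured effector and memory transcription factors, Bhlhe40 was at least 2.08-fold lower (416 against 879), a call lost with the doubled floor and with median-ratio scaling, the others were within 2-fold, and the median was -0.21 at percentile 54.1.

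Immediate early and heat shock genes were lower in 4 of 13 measured members, higher in 1 and within 2-fold in 8, with a median of -0.73 at percentile 4.09, inside the random range of -0.79 to 0.022. The AP-1 subunit Jund was 3.97-fold lower (1728 against 6861), and a second probe set gave a log2 ratio of -1.01. Tnfaip3, an inhibitor of NF-kappaB signalling, was at least 3.94-fold lower (404 against 1665), and the chaperone Hspa8 2.28-fold lower (3389 against 7741). Ier3 was the member in the other direction, at least 3.76-fold higher in memory (1588 against 398). The calls of Tnfaip3 and Ier3 were lost with the doubled floor. Outside this list, the stress-induced phosphatase subunit Ppp1r15a was 2.98-fold lower (873 against 2603) and the kinase gene Pim1 2.37-fold lower (2725 against 6448). The call of Jund was lost with quantile normalization (-0.55), and that of Pim1 with quantile (-0.51) and intensity-dependent normalization (-0.26). The list median shrank to -0.15 with quantile and -0.0048 with intensity-dependent normalization, under which Hspa8 turned to 0.068.

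Ribosomal protein genes were lower in 6 of 11 measured members and within 2-fold in 5, with a median of -1.19 at percentile 3.89, at the edge of the random range of -1.19 to -0.21. Rpl37a was 3.25-fold lower (3783 against 12311), Rps12 3.15-fold (3877 against 12197), Rplp0 2.90-fold (3183 against 9229) and Rps24 2.86-fold (3730 against 10668). Further bright transcripts of general cell function went with them. The elongation factor Eef1a1 was 4.38-fold lower (3593 against 15740), the translationally controlled protein Tpt1 3.41-fold (4420 against 15065), and the ferritin light chain Ftl1 2.90-fold (3573 against 10380). All of these sit at the top of the intensity range, where the brightest 87 probe sets had a median log2 ratio of -1.13 against -0.22 in the next 87. With quantile or intensity-dependent normalization no ribosomal gene was 2-fold lower, the calls of Eef1a1, Tpt1 and Ftl1 were lost as well, and with the latter Rps12, Rps24 and Tpt1 turned to 0.029, 0.041 and 0.16.

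**Figure D3:**
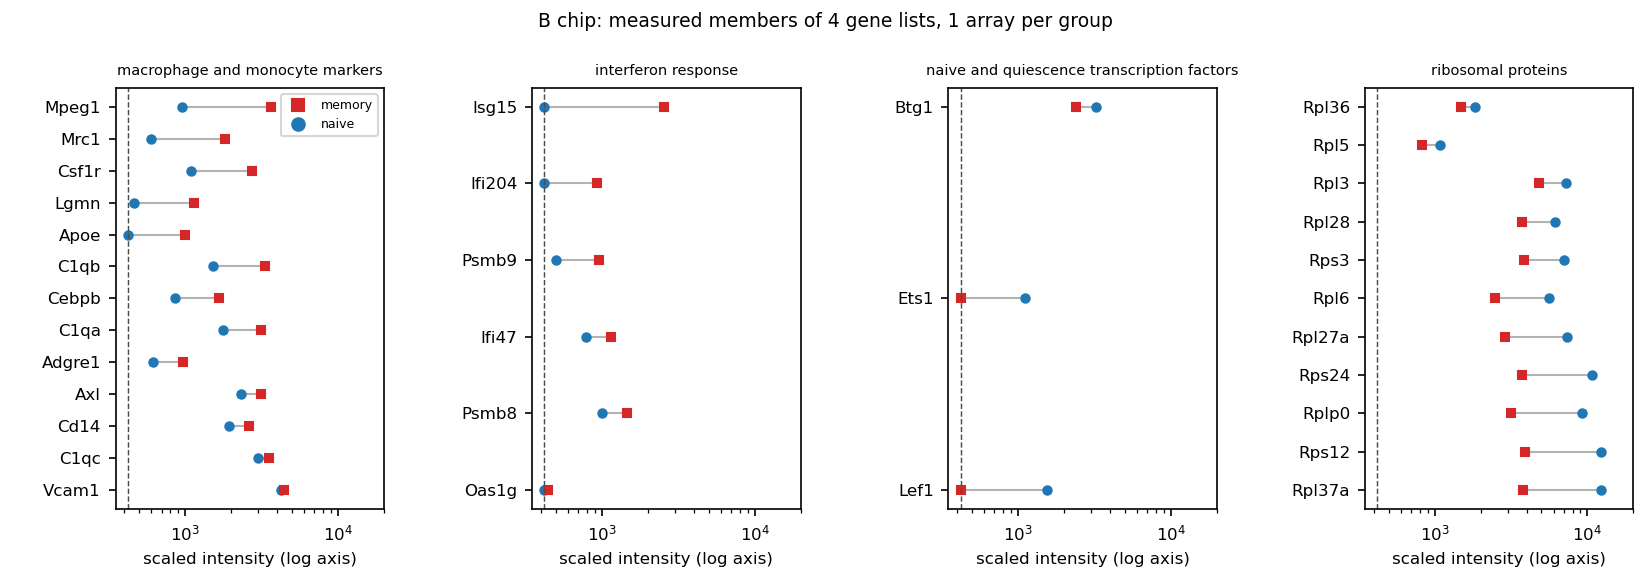
Scaled intensity (log axis) of each measured member of 4 gene lists on the B chip, with memory as red squares, naive as blue circles (1 array each), the noise floor as a dashed line, and values under the floor drawn at it. At least 2-fold differences were seen for 6 of 13 macrophage and 2 of 6 interferon genes (higher in memory), 2 of 3 transcription factors (Lef1 and Ets1, at the floor in memory) and 6 of 11 ribosomal genes (lower), the last with no 2-fold difference left, and Rps12 and Rps24 turned to 0.029 and 0.041, under intensity-dependent normalization.

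MHC class I presentation genes had 1 of 5 measured members lower, 4 within 2-fold and a median of -0.79 at percentile 11.6. The lower one was the class I heavy chain H2-D1, at 3.75-fold (2572 against 9639). It is another of the brightest transcripts, and its ratio moved to -0.69, inside 2-fold, with intensity-dependent normalization. The light chain B2m had a log2 ratio of -0.79, which turned to 0.55 with quantile and 0.44 with intensity-dependent normalization. The list median turned to 0.51 with quantile and 0.44 with intensity-dependent normalization.

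Of 4 measured cytotoxic granule genes, 3 lay within 2-fold and the median was -0.10 at percentile 50.6, turning to 0.045 with median-ratio, 0.47 with quantile and 0.46 with intensity-dependent scaling and moving to -0.58 without sequence-family probe sets. The exception was the protease granzyme A, Gzma, which was 2.03-fold lower in memory (1405 against 2848). Its call was lost without scaling and under each of the other scalings, where its log2 ratio of -1.02 became -0.998 to -0.871, just inside 2-fold. Gzma was also the only 1 of 3 measured NK cell markers past 2-fold, in a list with a median of -0.37 at percentile 3.25. The others, Klra4 (102 against 548) and Klra8 (279 against 516), were under the floor in memory, so their ratios are bounds. With the floor halved 2 of 4 measured NK cell markers were lower, the lowest at -1.37.

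Of 6 measured cell cycle and DNA replication genes, 1 was at least 2-fold lower and 5 lay within 2-fold with values under the floor set to it. The median of -0.42 lay at percentile 1.99, just outside the random range of -0.41 to 0.42. It falls between Hmgb2 (-0.64) and Ccne1 (-0.20), whose memory values lay under the floor. Only 2 of the 6 were above the floor on both arrays. Pcna, the sliding clamp of DNA polymerase, was 2.23-fold lower (573 against 1278) and was lost with the doubled floor. The 3 measured cell cycle inhibitors were within 2-fold with values under the floor set to it, with a median of -0.59 at percentile 6.31. Cdkn1a read 174 in memory, under the floor, against 648, so its -0.62 is only a bound. With the floor halved it was called lower, at -1.62.

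Among 11 measured chemokine receptor and migration genes, Lgals3 was the 1 past 2-fold, and the median was -0.21 at percentile 37.2, turning to 0.056 with quantile and 0.12 with intensity-dependent normalization. The 7 oxidative phosphorylation genes matched by symbol and the 6 glycolysis genes were all within 2-fold with values under the floor set to it. Their medians were 0.098 and -0.093 at percentiles 67.4 and 45.2. The oxidative phosphorylation gene Atp5a1, listed under its other symbol Atp5f1a, was not matched and not counted. It read 1458 in memory and 1301 in naive, a log2 ratio of 0.16. The glycolysis median turned to between 0.024 and 0.069 under the median-ratio, quantile and intensity-dependent scalings. Ndufv1, of oxidative phosphorylation, read 222 in memory, under the floor, against 452, and was called lower with the floor halved (-1.02). The 5 measured granulocyte genes were also within 2-fold, with a median of 0.15 at percentile 87.6. The neutrophil peptide Camp was bright in both preparations (3180 in memory, 5061 in naive), and its log2 ratio of -0.67 turned to 0.20 with quantile and 0.25 with intensity-dependent normalization. With quantile normalization 1 granulocyte gene, S100a8, passed 2-fold (1.03). Fewer than 3 members were measured, and no median is given, for NK receptors, apoptosis genes, B lineage markers and CD4 or regulatory T cell markers (2 each, with Pim1 the 1 changed member), and for T cell chemokines and lymph node homing genes (1 each). No member of the cytokine, cytokine receptor or stroma lists was measured.

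The second comparison asked how far separate probe sets give the same answer. On the B chip, 33 genes had 2 or more probe sets above the floor on both arrays, and their 2 brightest were compared. The direction was the same in 27 genes (81.8%), and the median absolute difference was 0.26 on the log2 scale. Probe sets under the floor on an array were left out. None of the 17 higher genes taken by the rule for named genes had a second measured probe set. Of the 23 lower ones only Jund, Tpt1 and Rplp0 had one, and these are bright transcripts. The check therefore does not cover the named increases. Across chips the A-chip ratios rest on the naive A values that hardly followed their genes, so the comparison does not test the B-chip ratios. There, 39 of 76 genes had the same direction on A and B (51.3%, exact 95% interval 39.6 to 63.0, across genes), with a median absolute difference of 1.33. The ratio of 3 prime to 5 prime control signal, a measure of RNA integrity, was 0.747 in memory and 1.17 in naive for actin on the B chip, and 1.76 and 1.25 for Gapdh. The 2 transcripts thus differed in opposite directions, by 1.57-fold and 1.41-fold. The naive actin signals (14928 and 12735) lay near the array maximum of 15798, so their ratio may not reflect RNA integrity alone.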

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

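The tests of the A-chip naming and of compressed bright signals, and the intensity-dependent scaling, were chosen only after the results were seen, and those of other cells, dim probe sets, RNA quality and scaling were planned.

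Signal outside the gene comparison separated the B-chip arrays. The bacterial transcripts BioB, BioC, BioDn and CreX, which are added to each sample as hybridisation controls, had a median log2 memory to naive ratio of -2.48 or lower over 9 probe sets, a bound because BioB was under the floor in memory. BioC read 722 in memory and 6036 in naive, and CreX 4635 and 14281. The 15 control probe sets without added transcript reached at most 118 and 240.

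The memory and naive values of the A chip hardly correlated. Naive A values out of register with their probe set names are a candidate explanation: naive A and naive B values of the same genes correlated at 0.073, no more than with shuffled names. Memory A and naive A correlated at 0.18, so part of the order may remain, although genes with more probe sets can raise that value. Pairs of probe sets of 1 sequence on the A chip correlated at -0.0072 on the naive array and 0.27 on the memory array. A biological difference between the cells would leave the arrays of 1 population alike, yet the control probe sets correlated at only 0.21 between the naive arrays, against 0.96 between the memory arrays. Weak hybridisation is argued against by the spread of the naive A signal, whose 98th percentile was 7.52 times the size of its 2nd percentile, above the 6.59 of the naive B array. Whether and how the values lost their order stays open.

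Of the 67 probe sets higher in memory on the B chip, 62.7% had a brighter array under 4 times the floor, so noise of dim probe sets may account for part of them, although 51.0% of all probe sets bright enough to be called were that dim. Other cells in the memory preparation cannot be told apart from a change in the T cells: the highest median among macrophage, dendritic cell, granulocyte and stroma lists was 0.94, under the limit of 1 set for it, but it was 1.09 with median-ratio, 1.33 with quantile and 1.10 with intensity-dependent scaling, 0.82 with the floor halved and 0.44 with it doubled, and the tissue of origin and the sort differed with the group. Vcam1 read 4443 in memory and 4217 in naive (log2 ratio 1.10 with intensity-dependent scaling) and Mpeg1 3665 and 954, and the bead sort was stated to leave a purity above 80%. RNA quality stays open as well, because control ratios differed by up to 1.57-fold and in opposite directions for actin and Gapdh. A biological difference between memory and naive cells stays open and was not tested.

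The split of 67 higher and 113 lower probe sets moved by 20.6 percentage points over the 4 scalings chosen beforehand, so the scaling could set it. Compression of bright signals on the memory array cannot be told apart from a lower level of bright transcripts. The highest deposited gene value was 5163 on the memory B array and 15668 on the naive B array, although their 98th percentiles were 2397 and 2630. On the A chip the highest values were 3232 and 9130. Either explanation allows such a lower top of the memory range. The log2 ratio of CreX exceeded that of the dimmer BioC by 1.46, the reverse of what compression on the memory array predicts. The added controls were, however, far dimmer on that array, with log2 ratios of -3.08 for BioC and -2.56 for BioDn, so the arrays read them on different parts of their range. On the naive array a CreX probe set gave the highest value of all, 15798. The mean signal rose 6.55-fold from BioB to CreX in naive and 23.5-fold in memory. The CreX ratio thus cannot speak against compression on the memory array. A lower share of ribosomal and other bright transcripts in memory cells stays open and was not tested further.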

How the results depend on the processing

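Intensity-dependent normalization and the removal of sequence-family probe sets were chosen only after the results were seen. The 17 named higher genes stayed higher under every scaling tried, and 12 with the doubled floor. Of the 23 named lower genes, 9 stayed lower with quantile and 9 with intensity-dependent normalization, 20 with median-ratio scaling and 18 with the doubled floor. No scaling and median-ratio scaling shift ratios towards memory, and the other normalizations raised the ratios of most bright genes. Higher calls could thus hardly be lost under the scalings, and the contrast with the lower genes does not show that they are firmer. Without sequence-family probe sets 24 of 40 named genes had a value. These 24 kept their call by construction, because their probe set, scaling and floor were unchanged. Median-ratio scaling moved the median ratio of all probe sets above the floor on both arrays from -0.15 to -0.019. With intensity-dependent normalization Tpt1 reversed to 0.16, Rps12 to 0.029, Rps24 to 0.041 and Hspa8 to 0.068. The other gene values stayed within 0.26 of the reported value in 285 cases and moved further in 56. Many of the 285 could not move further. No scaling and median-ratio scaling shift ratios above the floor by a constant smaller than 0.26. Settings that only select or average probe sets leave genes with a single probe set unchanged.

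Higher and lower counts on the B chip were 112 and 207 with the floor halved, 25 and 74 with it doubled or with the brighter array at least 4 times the floor, and 4 and 9 without class letters. They were 109 and 185 at 1.5-fold and 19 and 39 at 3-fold. The lower count was 73 with quantile normalization, 55 with intensity-dependent normalization (77 higher, 58.3% of the changed) and 45 without sequence families (48 higher, 51.6%). On the A chip they were 866 and 938 with the floor halved, 177 and 184 with it doubled or with the brighter array at least 4 times the floor, 51 and 144 without class letters, and 261 and 242 at 3-fold.

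The naive transcription factor median was -1.69 with quantile normalization, -0.78 and -0.44 with the floor halved and doubled, and reversed to 0.98 on the A chip and 0.19 with both chips pooled. The ribosomal median was -0.22 with quantile and -0.031 with intensity-dependent normalization, and reversed to 2.28 on the A chip and 1.93 pooled. The immediate early median was -0.15, -0.0048, 1.55 and -0.23 in the same order. The macrophage median was 1.33 with quantile normalization, 0.44 with the floor doubled and 2.04 on the A chip. The dendritic cell median was 0.74 with quantile normalization, 0.60 with the floor halved and 1.02 on the A chip. The interferon median was 0.45 with the floor doubled, and the NK marker median -0.98 with it halved. With both chips pooled the MHC class I median turned to 0.75, the cytotoxic one to 0.41, migration to 0.15, the T cell receptor complex to 0.10 and memory surface markers to -0.0078. The A-chip and pooled values use the naive A array; for the others the cause was not tested. Same-direction agreement between chips was 47.4% to 55.6% under its alternatives.

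Without class letters only the immediate early list kept 3 measured genes, and several short lists had no median with the floor doubled, without sequence families, or with genes above the floor on both arrays. No paired analysis was possible because each group had 1 array per chip, and leaving out an array would have left no comparison. Signal over background limited the comparison: 696 of 6540 B-chip probe sets were above the floor on both arrays.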

Other observations

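The descriptions of the A chip, which use the memory array only, and the intensity-dependent normalization were chosen after the results were seen. Memory A values followed their gene names by the correlations with both B arrays. On that array alone, 1407 of 4775 genes exceeded its own noise limit of 184, and levels of different probe sets are not compared. Ly6c2 read 1873, the survival gene Bcl2 688, the lymph node homing receptor Ccr7 505, the interleukin 7 receptor Il7r 354 and Cd3e 317, all above the limit. The interleukin 2 receptor beta chain Il2rb (148), granzyme B (Gzmb, 151) and interferon gamma (Ifng, 101) were not above it. The chemokines Ccl5 and Ccl4, which effector and memory CD8 T cells release, read 1269 and 1240, whereas 1 of 12 T cell cytokine genes, Ltb at 1023, exceeded the limit. Which cells of the preparation gave the chemokine signals was not tested.

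Interferon response genes were above the limit in 23 of 27 cases on the memory A array, with Rsad2 at 2033 and Irf7 at 1155. Macrophage markers were above it in 12 of 16 cases, among them Ctss (2409), Hmox1 (2228), Lyz2 (2007) and Spic (1800), a transcription factor of splenic red pulp macrophages. Mpeg1 (96) and Lgals3 (61, of the migration list), both called higher in memory on the B chip, were not above it. Ets1, under the floor in memory on the B chip, read 847. The granulocyte genes S100a8 and S100a9 read 2483 and 2162, with 5 of 13 of that list above the limit. Stroma markers were above it in 1 of 16 cases and B lineage markers in 3 of 16. Without a usable naive value, these levels say nothing of a difference between the groups.

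On the B chip the probe set for the mouse repeat element B2 read 2720 in memory and 14128 in naive, a log2 ratio of -2.38, while the one for the repeat B1 read 2893 and 3123. The B2 signal lies among the brightest probe sets, whose median log2 ratio was -1.13, and its ratio shrank to -1.45 with quantile and -0.85 with intensity-dependent normalization, while that of B1 turned from -0.11 to 0.43 and 0.41. The melanin synthesis gene Dct read 1251 and 5484, a 4.38-fold lower value in memory.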
